A study of Sus scrofa with 12 samples.

How the data were processed

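Liver RNA of 12 pigs was analysed, 3 from each of 4 groups that combine 2 breeds (Hezuo and Bama) with 2 housing temperatures (room temperature and cold), all taken on day 15 per the labels. The labels number the pigs 1 to 3 within each group, so the replicates are separate animals. Per the labels' protocols, total RNA was extracted with TRIzol, depleted of ribosomal RNA, fragmented and reverse-transcribed with random primers, and the strand made in the second synthesis step was digested before sequencing on an Illumina instrument, which keeps the strand of each RNA. The submitters' processing notes name fastp, a read-trimming tool. The aligner, the gene counter, the circRNA caller and the genome build are not given in the sources used here. Small RNAs and long non-coding RNAs as a separate class were not analysed here.

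The gene table holds estimated counts that the authors deposited per gene and library, not normalized, beside FPKM values that the authors deposited for the same genes. It lists 21169 gene rows, of which 21100 carry an Ensembl pig identifier and 69 an assembled identifier, and 4679 rows have no count in any library. Of the nonzero counts, 9.48% were fractional, as estimated counts can be, and they were rounded to whole numbers. Gene names came from the file for 14940 rows, from a table of Ensembl names for 889 and from the RefSeq annotation of the Sscrofa11.1 assembly for 706, and 4634 rows had no name. Of the identifiers, 14584 matched the table of Ensembl names, where 397 of 13695 rows named in both carried another symbol. The circRNA table holds counts of back-splice reads that the authors deposited per circRNA and library, beside RPM values that the authors deposited, which sum to 1000000 over the circRNAs of each library. A back-splice read crosses the junction where a later exon end is joined to an earlier exon start. The table lists 24177 circRNAs from 5763 host genes, each with at least 2 counts over all libraries and with a median of 7 counts. Of these, 79.1% are made of annotated exons, 8.4% of exons and introns, 4.0% of 1 exon, and 3.7% are antisense, 3.2% intergenic and 1.7% intronic. Coordinates are those of the deposited circRNA table, counted from 1. Of 18808 exonic circRNAs whose host gene was found in the RefSeq annotation of Sscrofa11.1, 98.2% lie inside that gene there. The FPKM and RPM columns were not used in any test.

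Pairs of replicates of 1 group correlated over genes at r = 0.97 to 0.984 on log2 CPM, and their chi-square per degree of freedom lay between 77.1 and 205.3, far above the sampling noise of 1 library counted again. No pair was merged.

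Each comparison of genes used edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM, with factors from 0.874 to 1.197, genes were kept by filterByExpr (minimum count 10, minimum total 15), and a robust quasi-likelihood model with 4 groups was fitted to all 12 libraries, leaving 8 residual degrees of freedom. Log2 fold changes are given with a standard error, taken as the absolute log2 fold change divided by the square root of the F statistic, and with a Benjamini-Hochberg adjusted p over all 13532 genes tested. A gene or circRNA was called where that p was below 0.05, with no threshold on the fold. The circRNAs were tested in the same way on back-splice counts, with TMM over circRNAs, for the 9032 that had at least 2 counts in at least 3 libraries and at least 10 counts in all. The 6 contrasts were cold against room temperature within each breed, Hezuo against Bama at each temperature, the difference between the breeds in the response to cold, and the response to cold averaged over both breeds. Levels are given as mean CPM with the SD over 3 libraries.

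There were 43 gene lists for metabolic pathways, stress and immune responses, and cell types that liver tissue can hold. They name 932 genes, of which 845 matched a row and 807 rows were tested. The 39 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. This test asks whether the genes of a list changed more than other genes did, with a preset correlation between genes of 0.01, and its p was adjusted over the lists of a comparison. The same test with an estimated correlation, and the fry test, which asks whether the genes of a list moved on balance in 1 direction, were run beside it. Single values per library (total circRNA reads per 1000000 gene counts, and circRNAs detected after thinning each library to 39117 back-splice reads, mean of 20 draws) were compared by exact permutation tests, two-sided, whose smallest possible p is 0.1 for 3 against 3 libraries and 0.005 for the 400 arrangements within breeds. Their p was adjusted over 12 tests.

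Genes were named by a fixed rule. Per comparison, it takes the 8 largest increases and 8 largest decreases among called genes that have a symbol, a mean of at least 1 CPM in the higher group and no overlap between the libraries compared. It adds the 4 called members of each list with the smallest p, and 15 fixed genes of cold response and liver metabolism in any case. The difference between the breeds in the response used the same rule without the condition on overlap, and where under 5 genes passed, the 5 with the smallest p each way are given as values. For circRNAs it takes the 5 smallest adjusted p each way and the 5 highest mean counts. Some genes that this rule gives are left out for length, and 3 are not reported here. The lists, this rule, the tests and the alternatives were fixed before the data were examined. Added later were 3 alternatives, the comparison of circRNA totals between the breeds over both temperatures, the tests of explanations, the splits of genes and circRNAs within each breed and between the breeds at room temperature, and the tolerance for a changed correlation.

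The alternatives fixed beforehand were the size factors of DESeq2 in place of TMM, the test of DESeq2 1.42.0, no filter on low counts, at least 1 CPM in 6 libraries, a replicate block, a fit on only the 2 groups compared, and leaving out each library in turn. For circRNAs they were also a library size from the gene counts and a minimum of 30 counts in all. Added after seeing the data were the presence of Y-linked RNA in a library as a covariate, the newer quasi-likelihood method of edgeR, and the breeds in the cold without Bama cold replicate 2. Where leaving out a library leaves a group of 2, that group is assumed to vary like the others.

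The procedure was tested on simulated counts made from the means and depths of the comparison of cold with room temperature in Hezuo pigs, with 50 genes changed at each of 4 sizes among 13411. edgeR recovered 4% of genes changed 1.5-fold, 38% of those changed 2-fold, 88% of those changed 4-fold and 96% of those changed 8-fold. Of its calls 3.4% (4 genes) were false. DESeq2 recovered 20%, 60%, 90% and 98% with 19.3% false calls. Of 50 simulated circRNAs at each size among 7673, edgeR recovered 0% at 1.5-fold and 2-fold and 8% at 4-fold and 8-fold, and DESeq2 recovered 0%, 0%, 8% and 6%. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.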

Results

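The livers of Hezuo and Bama pigs were profiled after 15 days at room temperature (23 ± 2 °C) or in the cold (-15 ± 2 °C) to find genes and non-coding RNAs tied to the cold resistance of the Hezuo breed. Hezuo pigs are a small Chinese breed of the high, cold Gansu plateau, and Bama pigs are a miniature breed from the warm south of China. RNA depleted of ribosomal RNA was sequenced from 3 pigs of each breed at each temperature, and the tables hold estimated counts per gene and back-splice counts per circRNA, a closed RNA loop made when a later exon end is joined to an earlier exon start. Gene counts totalled 30188037, 27527543 and 29085379 in Bama replicates 1 to 3 at room temperature, and 20041285, 23898318 and 27762477 in Bama in the cold. They totalled 26514977, 24586129 and 22688202 in Hezuo at room temperature, and 22700378, 24237379 and 27067726 in Hezuo in the cold. Back-splice counts were 68158, 54495 and 75616 in Bama at room temperature, 39117, 54778 and 55179 in Bama in the cold, 50704, 46071 and 46941 in Hezuo at room temperature, and 42562, 40165 and 52194 in Hezuo in the cold.

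The transcripts of ALB, which encodes serum albumin, made up 8.49% ± 0.223 (SD, n = 3) of gene counts in Bama pigs at room temperature and 3.93% ± 2.88 in the cold, with 1.53%, 3.14% and 7.12% in the 3 cold libraries. In Hezuo pigs they made up 11.03% ± 1.4 at room temperature and 6.73% ± 3.41 in the cold. The groups also differed in Y-linked RNA. DDX3Y, a gene of the Y chromosome, had 0 to 3 counts in the 3 Bama libraries at room temperature and in Bama cold replicate 2, against 2284 and 3769 in Bama cold replicates 1 and 3 and 1331 to 2407 in the 6 Hezuo libraries. The labels give no sex. The breeds parted on the first principal component of log2 CPM and the temperatures on the second.

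**Figure D1:**
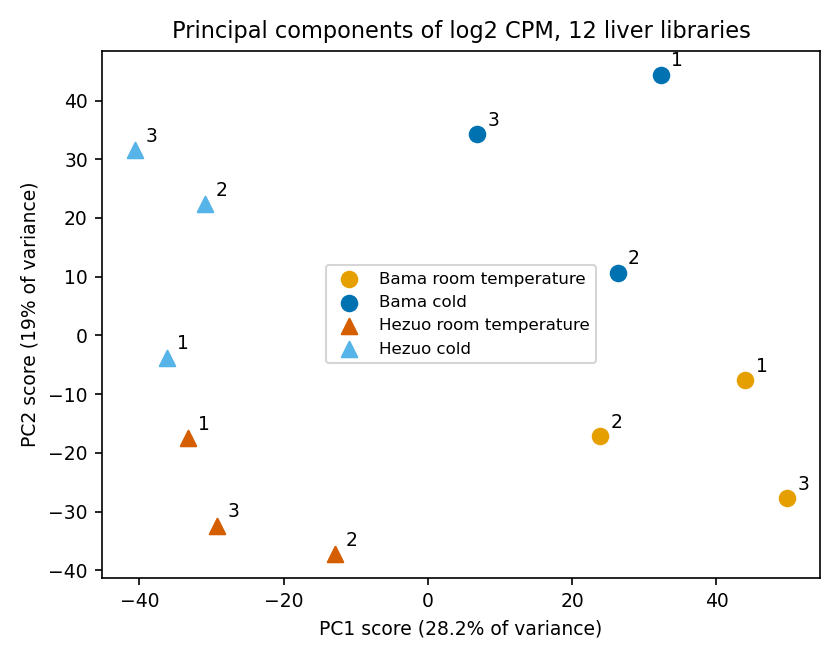
Principal components of log2 CPM over the genes tested, with 28.2% of the variance on the x axis and 19% on the y axis. Each point is 1 library, numbered by its replicate; circles are Bama and triangles Hezuo. Bama libraries span 6.8 to 49.8 and Hezuo libraries -40.6 to -12.9 on the x axis, and room temperature libraries span -37.2 to -7.6 and cold libraries -3.8 to 44.4 on the y axis.

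Cold exposure in Hezuo pigs was followed by higher RNA of genes that activate fatty acids and carry them into mitochondria. ACSL1, which joins fatty acids to coenzyme A, rose from 653 ± 60.9 to 3360 ± 1980 CPM (SD, n = 3), a log2 fold change of 2.36 ± 0.39 (SE; adjusted p = 0.0409). SLC25A20, the carrier of acylcarnitines across the inner mitochondrial membrane, rose from 25.8 ± 3.98 to 60.2 ± 6.03 CPM (1.22 ± 0.19, adjusted p = 0.0409), and PEX11A, which takes part in the division of peroxisomes, rose by 1.45 ± 0.26 (adjusted p = 0.0464). CPT1A, the gate of mitochondrial fatty acid oxidation, had means of 145 ± 28.6 and 494 ± 107 CPM and did not pass (1.77 ± 0.38, adjusted p = 0.0838). CYP8B1, the sterol 12-alpha-hydroxylase of bile acid synthesis, rose from 1.11 ± 1.11 to 92.8 ± 79 CPM (6.35 ± 0.98, adjusted p = 0.0409). CIDEC, a protein of lipid droplets, rose by 2.34 ± 0.4.

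Among genes that fell in Hezuo pigs in the cold were PER3, a component of the circadian clock, with a log2 fold change of -1.2 ± 0.21, and WEE1, a kinase that delays mitosis, with -1.35 ± 0.24. CORIN, the protease that activates natriuretic peptides, fell from a mean of 30.6 to 9.61 CPM (-1.67 ± 0.24) and ARVCF, a catenin, from 61.3 to 24.5 CPM (-1.33 ± 0.18). CIRBP and RBM3, RNA-binding proteins induced by cooling of cultured cells, had log2 fold changes of -0.25 ± 0.21 (adjusted p = 0.579) and -0.34 ± 0.33 (adjusted p = 0.647). The hormone gene FGF21 (0.97 ± 1.32), the bile acid enzyme gene CYP7A1 (0.52 ± 1.06) and UCP2 (-0.04 ± 0.35) did not pass either.

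Of 25 genes of fatty acid oxidation, 2 rose in Hezuo pigs over all genes tested and 12 rose adjusted over the list alone, with a median log2 fold change of 0.48 (camera adjusted p = 7.37e-10). Of 19 targets of PPARA, the fatty acid sensor of liver, 3 rose over all genes and 8 adjusted over the list alone (median 0.88, camera adjusted p = 5.73e-09). All 54 genes of cytosolic ribosomal proteins had negative fold changes (median -0.27, camera adjusted p = 3.46e-09), although edgeR called 0 of them by either adjustment, 9 had an unadjusted p below 0.05 and DESeq2 called 0. Lists of endoplasmic reticulum stress (median 0.64), heat shock chaperones (0.48), cholesterol synthesis and uptake (0.75), nuclear genes of the respiratory chain (0.15), immediate early genes (0.59), Kupffer cell and macrophage markers (0.54) and cell cycle (0.28) were also called upward. Adjusted over the list alone, 5 of 22 heat shock chaperones rose and 1 fell, and 1 of 24 endoplasmic reticulum stress genes and 1 of 29 cell cycle genes rose. In the cholesterol, nuclear respiratory chain, immediate early, Kupffer and stellate lists edgeR called 0 members by either adjustment, while 6 of 24, 14 of 72, 5 of 22, 4 of 19 and 5 of 20 had an unadjusted p below 0.05 and DESeq2 called 1, 2, 3, 0 and 0. Collagen and matrix (median -0.44, with 1 of 23 falling adjusted over the list alone), stellate cell markers (-0.37) and the circadian clock (-0.32) were called downward. Of 19 clock genes 1 fell over all genes tested, and adjusted over the list alone 6 fell and 1 rose. With an estimated correlation between genes, none of these 13 calls held (adjusted p = 0.617, and 0.734 for the cell cycle). In this and every other comparison here, 0 lists were called with an estimated correlation.

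In Hezuo pigs, edgeR called 38 of 13532 genes between the temperatures, 27 higher and 11 lower in the cold, and 2105 had an unadjusted p below 0.05. All 38 had no overlap between the 3 cold and the 3 room temperature libraries, against 21.8% of all genes tested and 10% by chance. DESeq2 called 540, a fit on only these 2 groups 60, and a fit with Y-linked RNA as a covariate, which was present in all 6 libraries here, 3. Without Hezuo room temperature replicate 1 or Hezuo cold replicate 3 edgeR called 0, with 2059 and 1485 genes at an unadjusted p below 0.05. The count was 2 without Hezuo room temperature replicate 2 or 3 or Hezuo cold replicate 2, and 3 without Bama cold replicate 2. It was 16 without Bama room temperature replicate 2, 20 without Bama cold replicate 1 and 66 without Bama room temperature replicate 3. None of the 38 passed in all 12 fits that left out 1 library. Among the lists, the call of heat shock chaperones was lost without Hezuo cold replicate 3 (adjusted p = 0.162), that of cholesterol synthesis without Hezuo cold replicate 2 (0.0872) and that of the clock without Hezuo room temperature replicate 1 (0.0547). Immediate early genes lost theirs without Hezuo room temperature replicate 1 (0.0547) or Hezuo cold replicate 3 (0.0661). Stellate markers lost theirs without Hezuo room temperature replicate 2 (0.0816) or Hezuo cold replicate 2 (0.0714). The cell cycle lost its call without Hezuo room temperature replicate 1 (0.2), Hezuo cold replicate 1 (0.102) or Hezuo cold replicate 2 (0.186).

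In Bama pigs the cold was accompanied by higher RNA of genes that break down amino acids. HPD and HGD, successive enzymes of tyrosine breakdown, rose from 390 ± 88.3 to 1500 ± 305 CPM (1.94 ± 0.24, adjusted p = 0.00586) and from 50.2 ± 35.9 to 347 ± 100 CPM (2.79 ± 0.44, adjusted p = 0.02). TDO2, which opens the breakdown of tryptophan, rose from 284 ± 28.2 to 668 ± 55.1 CPM (1.24 ± 0.19, adjusted p = 0.0171) and SDSL, a serine dehydratase, by 1.34 ± 0.27. FKBP5, a target of the glucocorticoid receptor, rose from a mean of 37.7 to 134 CPM (1.83 ± 0.33, adjusted p = 0.033). SLC1A2, a glutamate transporter, rose from 31.6 to 181 CPM, and POR, the electron donor of cytochromes P450, from 125 to 251 CPM. PERM1, a regulator of oxidative metabolism known from muscle, rose from 2 to 14.6 CPM, and DNER from 0.26 to 5.34 CPM.

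Among genes that fell in Bama pigs in the cold was FADS2, the delta-6 desaturase of polyunsaturated fatty acid synthesis, from 384 ± 30.5 to 53.5 ± 17.7 CPM (-2.84 ± 0.38, adjusted p = 0.00967). IGFALS, which stabilizes circulating IGF1, fell from 65.1 ± 13.1 to 15.9 ± 4.3 CPM (-2.03 ± 0.22, adjusted p = 0.00242). COL3A1 fell from 1450 ± 488 to 457 ± 125 CPM (-1.67 ± 0.33, adjusted p = 0.043) and COL1A2 from a mean of 447 to 139 CPM, both fibrillar collagens. ACADL and DECR2, enzymes of fatty acid oxidation, fell by 1.02 and 0.87 on the log2 scale, and SERPINA1, the major protease inhibitor of plasma, from 1490 to 692 CPM. RBM3 (-1.29 ± 0.33, adjusted p = 0.0963), CIRBP (-0.08 ± 0.21, adjusted p = 0.878) and CPT1A (-0.12 ± 0.37, adjusted p = 0.908) did not pass.

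Of 29 genes of the urea cycle and amino acid catabolism, 4 rose in Bama pigs over all genes tested and 14 adjusted over the list alone (median 0.81, camera adjusted p = 2.57e-11). Among 30 interferon response genes, edgeR called 0 over all genes tested, 14 rose adjusted over the list alone, 17 had an unadjusted p below 0.05 and DESeq2 called 6 (median 0.79, camera adjusted p = 9.03e-07). Collagen and matrix fell, with 2 of 23 genes over all genes tested and 12 adjusted over the list alone (median -0.68, camera adjusted p = 7.83e-08), as did stellate and mesenchymal markers, with 2 of 20 and 6 (median -0.33, camera adjusted p = 0.0012). Hepatocyte markers were called downward (median -0.38, camera adjusted p = 0.00258), with 2 of 22 falling over all genes, and 9 falling and 2 rising adjusted over the list alone. The growth hormone and IGF axis was called downward (median -0.3, camera adjusted p = 0.0414), with 1 of 16 falling over all genes, and 5 falling and 1 rising adjusted over the list alone. Kupffer cell markers (median 0.4, with 1 of 19 rising adjusted over the list alone), periportal hepatocyte genes (0.65), glucocorticoid response (0.23), heat shock chaperones (0.29) and the nuclear (0.1) and mitochondrial (0.35) genes of the respiratory chain were called upward. In the last 3 edgeR called 0 members by either adjustment, while 5 of 22, 17 of 72 and 1 of 13 had an unadjusted p below 0.05 and DESeq2 called 0, 5 and 0. Of 15 periportal genes 1 fell over all genes tested, and 6 rose and 2 fell adjusted over the list alone; of 20 glucocorticoid response genes 2 rose over all genes, and 3 rose and 1 fell over the list alone. Cytosolic ribosomal proteins (median -0.35) and the cell cycle (-0.62) were called downward, while edgeR called 0 members of either by either adjustment, 16 of 54 and 5 of 29 had an unadjusted p below 0.05 and DESeq2 called 2 of each. With an estimated correlation, adjusted p = 0.698 for these lists, and 0.823 for heat shock chaperones and the mitochondrial genes. The list of fatty acid oxidation, called in Hezuo pigs, had a median of 0.02 in Bama pigs (camera adjusted p = 0.986).

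In Bama pigs, edgeR called 125 genes between the temperatures, 52 higher and 73 lower in the cold, and 2137 had an unadjusted p below 0.05. Libraries of the groups did not overlap for 121 of the 125 and for 21.3% of all genes tested, against 10% by chance. Y-linked RNA was present in 0 of 3 Bama libraries at room temperature and 2 of 3 in the cold. Its part cannot be fully told apart from that of cold here. With it as a covariate the Bama cold group rests on replicate 2 alone, so that fit cannot separate them. DESeq2 called 682 and a fit on only these 2 groups 12. The count was 51 and 18 without Bama room temperature replicates 1 and 3, and 32 (19 higher) and 24 (13 higher) without Bama cold replicates 1 and 3. It was 75 and 63 without Hezuo room temperature replicates 1 and 3, 81 without Hezuo cold replicate 2 and 133 without Bama cold replicate 2, the cold library without Y-linked RNA. Without Bama room temperature replicate 2 it was 129, and the balance turned to 81 higher and 48 lower. HPD, IGFALS, FADS2 and DNER were among the 14 genes called in all 12 fits that left out 1 library. Among the lists, calls were lost without Bama room temperature replicate 1 for periportal genes (adjusted p = 0.0606), glucocorticoid response (0.0642) and the mitochondrial genes (0.143). They were lost without Bama room temperature replicate 2 for Kupffer cell markers (0.0555), nuclear respiratory chain genes (0.0751), the IGF axis (0.175) and heat shock chaperones (0.274). Without Bama room temperature replicate 3 they were lost for the mitochondrial genes (0.0627), glucocorticoid response (0.154) and periportal genes (0.189). They were lost without Bama cold replicate 1 for glucocorticoid response (0.0713) and Kupffer cell markers (0.148), without Bama cold replicate 2 for periportal genes (0.0708), and without Bama cold replicate 3 for the IGF axis (0.104) and heat shock chaperones (0.227). The call of heat shock chaperones was also lost without Hezuo room temperature replicate 2 (0.0531) or 3 (0.0515), and that of the IGF axis without Hezuo room temperature replicate 1 (0.0509) or 2 (0.0514) or Hezuo cold replicate 1 (0.0549) or 3 (0.106).

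Averaged over both breeds, several genes of mitochondrial and nitrogen metabolism were higher in the cold. AGXT, which converts glyoxylate to glycine, rose from means of 35.4 to 192 CPM in Bama and from 42.1 to 264 CPM in Hezuo pigs (2.54 ± 0.4, adjusted p = 0.0128). APOA5, a regulator of triglyceride clearance, rose from 247 to 775 CPM and from 179 to 1390 CPM (2.3 ± 0.41, adjusted p = 0.0203). HNF4A, a transcription factor that maintains the hepatocyte state, rose from 161 to 391 CPM and from 270 to 434 CPM (0.98 ± 0.24, adjusted p = 0.0452). ESRRA, a regulator of mitochondrial genes, rose from 39 to 64.2 CPM and from 49.7 to 74.6 CPM (0.65 ± 0.11, adjusted p = 0.0156). FKBP5 and KLF9, both targets of the glucocorticoid receptor, rose by 1.46 ± 0.23 and 0.7 ± 0.16, PERM1 by 2.55 ± 0.39 and GLTPD2 by 2.35 ± 0.26. The amino acid genes SLC1A2, HGD and HPD rose by 1.91 ± 0.26, 1.85 ± 0.3 and 1.15 ± 0.17. VSIG4, a receptor of resident macrophages, rose from 82.2 to 168 CPM and from 85.2 to 129 CPM (0.82 ± 0.16, adjusted p = 0.0215). COX7B and UQCRC1, subunits of the respiratory chain, rose by 0.44 ± 0.08 and 0.43 ± 0.09.

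Lower in the cold over both breeds were the collagens COL1A1 (-1.63 ± 0.34), COL1A2 (-1.26 ± 0.24), COL3A1 (-1.25 ± 0.23) and COL6A6 (-2.23 ± 0.43) and the matrix proteoglycan DCN (-1.21 ± 0.27). COL1A1 fell from means of 720 to 150 CPM in Bama and from 398 to 200 CPM in Hezuo pigs (adjusted p = 0.0304). The clock genes PER2 and PER3 fell by 1.05 and 0.87 on the log2 scale, with means of PER2 going from 24.7 to 12.8 CPM and from 42 to 18.9 CPM (adjusted p = 0.0156), while CLOCK rose by 0.37 ± 0.09 (adjusted p = 0.0456). SERPINA1 was at -0.85 ± 0.14, AHSG at -0.91 ± 0.22 and the acute-phase protein gene ORM1 at -1.28 ± 0.31, while acute-phase proteins as a list were not called (camera adjusted p = 0.345). IGFALS fell by 1.4 ± 0.15 and SPATA20 by 1.47 ± 0.16 (adjusted p = 0.00216 for both). RBM3 (-0.82 ± 0.23, adjusted p = 0.0704) and CIRBP (-0.17 ± 0.15, adjusted p = 0.524) did not pass.

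**Figure D2:**
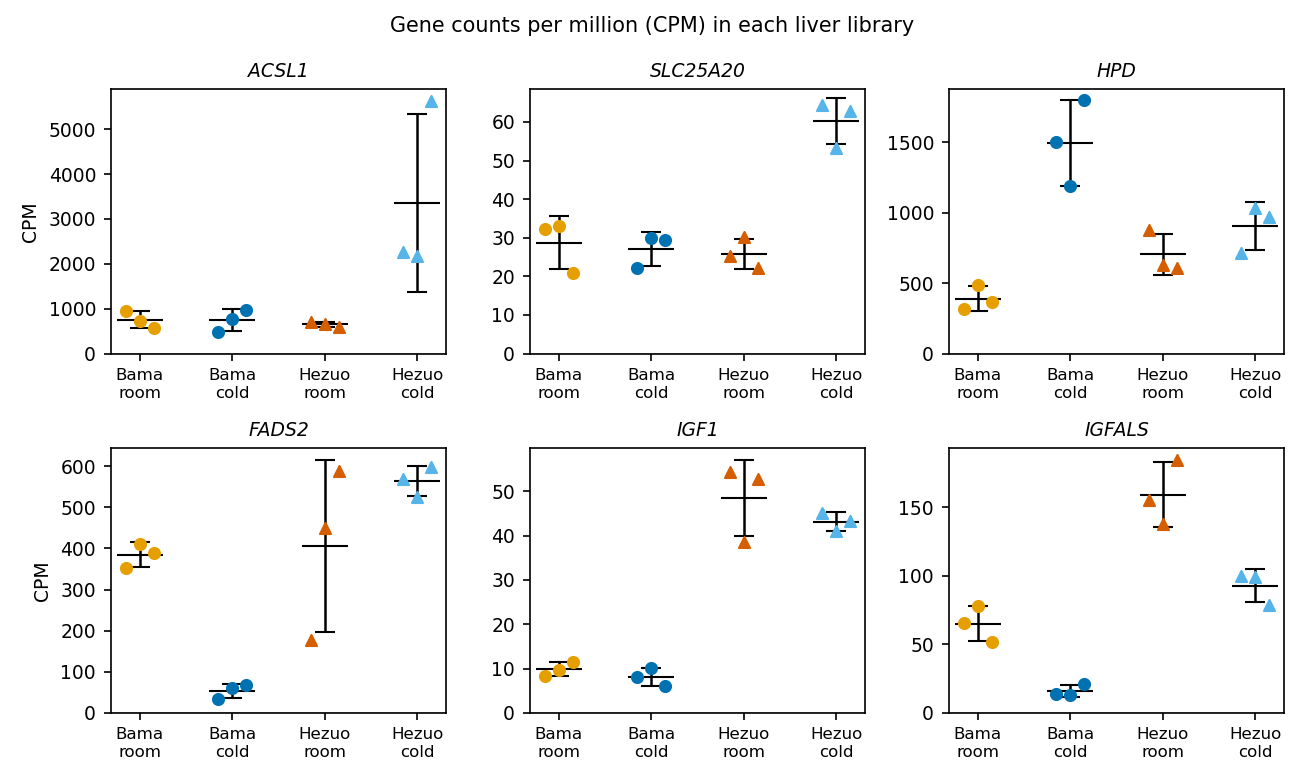
CPM per library for ACSL1, SLC25A20, HPD, FADS2, IGF1 and IGFALS in Bama and Hezuo livers at room temperature and in the cold; points are single pigs, and bars give the mean and SD (n = 3) on linear axes that start at 0. HPD in Bama pigs rises from 390 to 1500 CPM in the cold, FADS2 in Bama pigs falls from 384 to 53.5 CPM, and ACSL1 in Hezuo pigs rises from 653 to 3360 CPM.

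Cytosolic ribosomal proteins (median -0.32, camera adjusted p = 9.6e-14) and collagen and matrix (-0.51, 5.99e-08) fell in the cold over both breeds, with 1 of 54 and 6 of 23 genes falling over all genes tested and 6 and 14 adjusted over the list alone. Stellate markers fell too (-0.31, 0.000554), with 5 of 20 and 6. The urea cycle and amino acid catabolism (median 0.54, 9.78e-06; 4 of 29 rose over all genes, 6 rose and 1 fell adjusted over the list alone) and nuclear respiratory chain genes (0.12, 4.29e-05; 4 of 72 and 16 rose) were called upward. Fatty acid oxidation was called upward (0.29, 0.000157), with 3 of 25 rising and 1 falling over all genes, and 11 rising and 2 falling adjusted over the list alone. PPARA targets (0.35, 0.00432; 2 of 19 and 5 rose) and Kupffer cell markers (0.42, 0.000157; 1 of 19 and 3 rose) were called upward as well. Heat shock chaperones (0.41, 0.00302) had 1 of 22 rising over all genes, and 10 rising and 2 falling adjusted over the list alone. Periportal genes (0.54, 0.00879) had 1 of 15 rising and 1 falling over all genes, and 4 rising and 2 falling over the list alone. Interferon response (0.47, 0.000273; 1 of 30 rose by either adjustment) and glucocorticoid response (0.31, 0.0244; 2 of 20 rose by either) were called upward. Hepatocyte markers were called downward (-0.29, 0.0116), with 1 of 22 rising and 4 falling over all genes, and 1 and 8 over the list alone. With an estimated correlation, adjusted p = 0.579 for these lists, 0.612 for heat shock chaperones and 0.656 for interferon response. These calls held in all 12 fits that left out 1 library except that of glucocorticoid response, lost without Bama room temperature replicate 1 (adjusted p = 0.0522) or 3 (0.0634) or Hezuo cold replicate 3 (0.0868). Within breeds, urea cycle, interferon, glucocorticoid, periportal and hepatocyte lists were called in Bama pigs only. Urea cycle and interferon medians were 0.15 and 0.2 in Hezuo pigs. Fatty acid oxidation and PPARA targets were called in Hezuo only. A further 6 lists were called but lost their call without at least 1 library: endoplasmic reticulum stress and mitochondrial genes of the respiratory chain (0.36 and 0.35; in edgeR 0 of 24 and 0 of 13 by either adjustment, 1 and 3 at an unadjusted p below 0.05, and 0 in DESeq2), antioxidant defence (0.17), the circadian clock (-0.26), drug-metabolizing enzymes (-0.4) and the IGF axis (-0.2).

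Over both breeds, edgeR called 526 genes for cold, 264 higher and 262 lower, and 3182 had an unadjusted p below 0.05. DESeq2 called 1491, and edgeR with Y-linked RNA as a covariate 6. The count was 338 and 130 without Bama room temperature replicates 1 and 3, and 260 and 236 without Bama cold replicates 1 and 3. It was 312, 145 and 260 without Hezuo room temperature replicates 1 to 3, and 197 and 178 without Hezuo cold replicates 2 and 3. FKBP5, HPD, HGD, AGXT, PERM1, GLTPD2, SLC1A2, ESRRA, COL3A1, IGFALS, SERPINA1, PER2 and PER3 were among the 108 called in all 12 of these fits.

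At room temperature the breeds differed in genes of growth hormone signalling, of amino acid breakdown and of lymphocytes. IGF1, the growth factor that liver releases under growth hormone, was higher in Hezuo than in Bama livers at 48.6 ± 8.63 against 9.83 ± 1.63 CPM (SD, n = 3; 2.3 ± 0.2, adjusted p = 0.000693). Its binding partner IGFALS was higher at 159 ± 23.6 against a mean of 65.1 CPM (1.29 ± 0.21, adjusted p = 0.0265), and the growth hormone receptor GHR at 284 against 126 CPM (1.17 ± 0.24, adjusted p = 0.0457). AADAT, an aminotransferase of lysine and kynurenine breakdown, had 48.8 ± 22.7 CPM in Hezuo and a mean of 0.0649 CPM in Bama livers (9.42 ± 0.6, adjusted p = 8.11e-05). TDO2, FAH of tyrosine breakdown and GAMT of creatine synthesis were higher by 1.03 ± 0.19, 0.93 ± 0.19 and 0.85 ± 0.14. PLIN4, a coat protein of lipid droplets, was higher by 1.74 ± 0.32, TEF, a clock-controlled transcription factor, by 1.15 ± 0.24 and SDHB, a subunit of succinate dehydrogenase, by 0.73 ± 0.14. MT1A, a metallothionein, had 4540 against 2000 CPM, a value uncertain because similar copies exist. The Y-linked genes DDX3Y and EIF1AY were called as well (adjusted p = 0.0462 and 0.0455).

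Lower in Hezuo livers at room temperature were CD8A, a coreceptor of cytotoxic T cells, at 7.36 ± 1.07 against 39.2 ± 21.4 CPM (-2.41 ± 0.39, adjusted p = 0.0311), and THEMIS of T cell development (-2.27 ± 0.33, adjusted p = 0.018). CD209, a lectin of dendritic cells and macrophages, had 0.152 against 25.6 ± 24 CPM (-7.36 ± 1.4), and IDO1, an interferon-induced enzyme of tryptophan breakdown, 0.25 against 3.18 CPM (-3.67 ± 0.75). KIF20A, a kinesin of cell division, was lower at -1.85 ± 0.39 and APOM, an apolipoprotein of high-density lipoprotein, at -0.94 ± 0.2.

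Of 29 cell cycle genes, 1 was lower in Hezuo livers at room temperature over all genes tested and 24 adjusted over the list alone (median -1.25, camera adjusted p = 6.54e-13). T and NK cell markers were lower (median -1.32, camera adjusted p = 2.15e-07), with 1 of 22 lower over all genes, and 18 lower and 1 higher adjusted over the list alone. Interferon response (-0.79, camera adjusted p = 4.51e-08) and antigen presentation (-0.83, camera adjusted p = 3.57e-05) were called lower. Here edgeR called 0 of their 30 and 17 genes over all genes tested, 18 and 10 were lower at an unadjusted p below 0.05, and DESeq2 called 6 and 8 lower. Adjusted over the list alone, 6 and 9 were lower and 1 antigen presentation gene was higher. The urea cycle and amino acid catabolism was higher (median 0.85, camera adjusted p = 2.72e-11), with 2 of 29 over all genes and 13 adjusted over the list alone. The IGF axis was called higher (0.2, camera adjusted p = 0.0236), with 3 of 16 over all genes, and 4 higher and 1 lower over the list alone. Pericentral hepatocyte genes (median 0.41), hepatocyte markers (0.42), gluconeogenesis and glycogen (0.44), drug-metabolizing enzymes (0.51) and the circadian clock (0.67) were called higher. Adjusted over the list alone, 4 of 15 pericentral genes, 1 of 23 gluconeogenesis genes and 7 of 19 clock genes were higher, as were 4 of 21 drug-metabolizing genes against 1 lower, and 0 of 22 hepatocyte markers passed either adjustment (7 at an unadjusted p below 0.05, 3 in DESeq2). With an estimated correlation, adjusted p = 0.487 for these lists, and 0.556 for interferon response and antigen presentation. These 11 calls held in all 12 fits that left out 1 library. A further 10 lists were called with an adjusted p that rose above 0.05 without at least 1 library, among them fatty acid oxidation (0.27; adjusted p = 0.0761 without Bama room temperature replicate 3). Another was collagen and matrix (-0.35; 0.528 without Bama room temperature replicate 3, 0.0957 and 0.276 without Hezuo room temperature replicates 1 and 3). The collagen list turned to the other direction with Y-linked RNA as a covariate (adjusted p = 0.678), and with an estimated correlation adjusted p = 0.718 and 0.781 for these 2 lists. In both edgeR called 0 members by either adjustment, with 8 of 25 and 3 of 23 at an unadjusted p below 0.05 and 3 and 1 in DESeq2.

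At room temperature edgeR called 146 genes between the breeds, 91 higher and 55 lower in Hezuo pigs, and 2683 had an unadjusted p below 0.05. For all 146 the libraries of the breeds did not overlap, against 23.8% of all genes tested and 10% by chance. Y-linked RNA was present in all 3 Hezuo and 0 of 3 Bama libraries here; with it as a covariate, informed by the Bama cold libraries alone, edgeR called 3 genes. DESeq2 called 1036, and the newer method of edgeR 231. The count was 593 without Bama room temperature replicate 2, where the balance turned to 240 higher and 353 lower. It was 8 and 10 without Hezuo room temperature replicates 1 and 3, and 12 and 22 without Bama room temperature replicates 1 and 3. It was 72 without Hezuo cold replicate 2, 85 without Hezuo room temperature replicate 2 and 90 without Hezuo cold replicate 1. IGF1 and AADAT were among the 8 genes called in all 12 fits that left out 1 library.

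In the cold, genes of fatty acid oxidation and of growth hormone signalling were higher, and interferon-induced genes lower, in Hezuo than in Bama livers. ACADL, a long-chain acyl-CoA dehydrogenase, had 76.1 ± 7.42 against 21.8 ± 4.49 CPM (SD, n = 3; 1.8 ± 0.18, adjusted p = 0.000984). ACSL1 had 3360 ± 1980 against 742 ± 243 CPM (2.18 ± 0.38, adjusted p = 0.0199), and the peroxisomal oxidation genes ACAA1 and EHHADH were higher by 1.33 ± 0.2 and 0.89 ± 0.19. SLC25A20 was higher by 1.15 ± 0.19, and CPT1A had 494 against 173 CPM without passing (1.51 ± 0.38, adjusted p = 0.0557). FADS2 had 565 ± 36.4 against 53.5 ± 17.7 CPM (3.4 ± 0.39, adjusted p = 0.00324), and ELOVL2, which elongates polyunsaturated fatty acids, was higher by 4.18 ± 0.81. CYP8B1 had 92.8 ± 79 against 1.25 CPM (6.17 ± 0.95), and the bile acid genes SCP2 and AKR1D1 were higher by 1.01 ± 0.19 and 0.96 ± 0.19. DGAT1 and DGAT2, which complete triglyceride synthesis, were higher by 1.17 ± 0.24 and 1.62 ± 0.34, and the lipid droplet genes CIDEC and PLIN4 by 2.45 ± 0.4 and 1.56 ± 0.32.

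IGF1 had 43.2 ± 2.06 against 8.08 ± 2.09 CPM in the cold (2.42 ± 0.21, adjusted p = 0.000359) and IGFALS a mean of 92.7 against 15.9 CPM (2.54 ± 0.22, adjusted p = 0.000359). GHR was higher by 1.48 ± 0.24, and the binding protein gene IGFBP2 was lower (-1.19 ± 0.23, adjusted p = 0.0262). AADAT had 120 ± 43 against 0.0886 CPM (10.38 ± 0.6, adjusted p = 2.77e-05). STAB2, a scavenger receptor of liver sinusoids, was higher by 1.09 ± 0.19, and LRAT, which stores vitamin A in stellate cells, by 1.49 ± 0.33. Among interferon-induced genes, IFI44 had 15.3 ± 3.44 against 51 ± 22 CPM (-1.73 ± 0.27, adjusted p = 0.0121), EIF2AK2 a mean of 62.8 against 156 CPM (-1.31 ± 0.21, adjusted p = 0.0121). IFI44L, ZBP1 and DHX58 were at -1.39 ± 0.26, -1.21 ± 0.24 and -4.69 ± 1.04. The T cell genes CD5 and CD8A were at -2.1 ± 0.4 and -1.88 ± 0.39, and IDO1 at -3.08 ± 0.72.

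Of 25 genes of fatty acid oxidation, 13 were higher in Hezuo than in Bama livers in the cold over all genes tested and 21 adjusted over the list alone (median 0.67, camera adjusted p = 8.77e-17). Of 30 interferon response genes, 11 were lower over all genes tested and 28 adjusted over the list alone (median -1.33, camera adjusted p = 4.56e-16). PPARA targets (median 0.93; 3 of 19 over all genes, 11 over the list alone), hepatocyte markers (0.5; 1 of 22 and 10), bile acid synthesis and transport (0.36; 3 of 19 and 7) and gluconeogenesis and glycogen (0.41; 2 of 23 and 4) were called higher. Lipoprotein genes (0.36) had 2 of 25 higher over all genes, and 7 higher and 2 lower adjusted over the list alone. Pericentral genes (0.47) had 3 of 15 higher, and 5 higher and 1 lower over the list alone, and adipocyte markers (0.61) had 3 of 8 higher by either adjustment. Drug-metabolizing enzymes (0.38) had 2 of 21 higher, and 6 higher and 1 lower over the list alone. The IGF axis (0.26, camera adjusted p = 0.0221) had 4 of 16 higher and 1 lower by either adjustment. T and NK cell markers were lower (-0.95; 2 of 22 and 10), as was antigen presentation (-0.67), where edgeR called 0 of 17 genes by either adjustment, 9 were lower at an unadjusted p below 0.05 and DESeq2 called 1. With an estimated correlation, adjusted p = 0.326 for fatty acid oxidation, interferon response, PPARA targets, hepatocyte markers, lipoprotein genes, pericentral genes, adipocyte markers and the IGF axis, 0.401 for bile acid, gluconeogenesis, drug-metabolizing and T and NK cell genes, and 0.548 for antigen presentation. The call of the IGF axis was lost without Bama cold replicate 3 (adjusted p = 0.083) or Hezuo cold replicate 3 (0.106), and the others named here held in all 12 fits that left out 1 library. In all, 18 lists were called in this comparison. Triglyceride synthesis (median 0.22, 4 of 22 higher over all genes, 7 over the list alone) lost its call without Bama cold replicate 1 (0.325) or 2 (0.0868) or Hezuo cold replicate 1 (0.075) or 2 (0.0607), with adjusted p = 0.656 with an estimated correlation.

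In the cold edgeR called 374 genes between the breeds, 244 higher and 130 lower in Hezuo pigs, and 2852 had an unadjusted p below 0.05. Libraries did not overlap for 373 of the 374 and for 25.2% of all genes tested, against 10% by chance. Y-linked RNA was present in 3 of 3 Hezuo and 2 of 3 Bama libraries, and the count was 132 with it as a covariate. DESeq2 called 1227 and a fit on only these 2 groups 116. The count was 69 and 131 without Bama cold replicates 1 and 2. It was 107, 154 and 84 without Hezuo cold replicates 1 to 3, and 240 without Hezuo room temperature replicate 1. AADAT, IGF1, IGFALS, ACADL, ACAA1 and FADS2 were among the 47 genes called in all 12 fits that left out 1 library.

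Whether the breeds differed in their response to cold was tested as the difference between the 2 responses. MAGED1, an adaptor protein of neurotrophin signalling and cell death, was the single gene that edgeR called of 13532. Its means were 84.3 ± 18 CPM at room temperature and 32.6 ± 0.989 CPM in the cold in Bama pigs, and 36.8 ± 4.88 and 70.9 ± 7.33 CPM in Hezuo pigs (2.32 ± 0.23, adjusted p = 0.00512). It was called in all 12 fits that left out 1 library. The next genes by p did not pass. Among them were the lipid droplet gene PLIN3 (2.52 ± 0.38), FADS2 (3.32 ± 0.52), TDO2 (-1.74 ± 0.27) and ARVCF (-1.57 ± 0.25), all with adjusted p = 0.07. CPT1A had 1.89 ± 0.53 (adjusted p = 0.349). In all, 1085 genes had an unadjusted p below 0.05, DESeq2 called 139, and with Y-linked RNA as a covariate edgeR called 0, with 737 at an unadjusted p below 0.05. The count was 23 without Bama room temperature replicate 3, 11 without Bama cold replicate 2 and 5 without Bama room temperature replicate 2, and 1 to 3 without any other library.

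By list, the response of Hezuo pigs lay above that of Bama pigs for PPARA targets (median difference 1.1, camera adjusted p = 2.68e-10), fatty acid oxidation (0.52, 1.73e-09), cell cycle (0.97, 4.34e-09). It lay above for cholesterol synthesis and uptake (0.86, 5.67e-07), immediate early genes (1.11, 5.89e-05), endoplasmic reticulum stress (0.58, 0.000712) and lipoprotein genes (0.13, 0.0376). It lay below for the urea cycle and amino acid catabolism (-0.8, 1.73e-09) and interferon response (-0.56, 0.000261). edgeR called 0 members of these lists over all genes tested. At an unadjusted p below 0.05, 10 of 19 PPARA targets and 11 of 25 fatty acid oxidation genes lay above, and DESeq2 called 6 in each. Adjusted over the list alone, 9 PPARA targets, 9 fatty acid oxidation genes and 1 gene each of the cell cycle, cholesterol and endoplasmic reticulum stress lists lay above. Of 29 urea cycle and amino acid genes 3 lay below, and 4 of 25 lipoprotein genes lay above and 1 below. Of immediate early and interferon response genes 0 passed, with 6 of 22 and 6 of 30 at an unadjusted p below 0.05 and 1 and 0 in DESeq2. With an estimated correlation, adjusted p = 0.684 for PPARA targets, 0.973 for interferon response and endoplasmic reticulum stress, and 0.806 for the other 6. The call of interferon response was lost without Bama cold replicate 1 (adjusted p = 0.246), that of endoplasmic reticulum stress without Bama room temperature replicate 1 (0.0932) or Hezuo cold replicate 3 (0.0837). Lipoprotein genes lost theirs without Bama room temperature replicate 2 (0.0919), Bama cold replicate 1 (0.323), Hezuo room temperature replicate 2 (0.0685) or 3 (0.078) or Hezuo cold replicate 1 (0.0935). In all, 15 lists were called without Bama room temperature replicate 2 and 14 without Hezuo room temperature replicate 1. Across all 13532 genes, the 2 responses correlated at Pearson r = 0.273 and Spearman rho = 0.354. Genes are not independent replicates, so no p is given, and no library is shared between the 2 responses. On mean log2 CPM the correlation was 0.334, and 4 of 100 pairs of splits of the 2 breeds, the real pair included, gave a value as large.

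**Figure D3:**
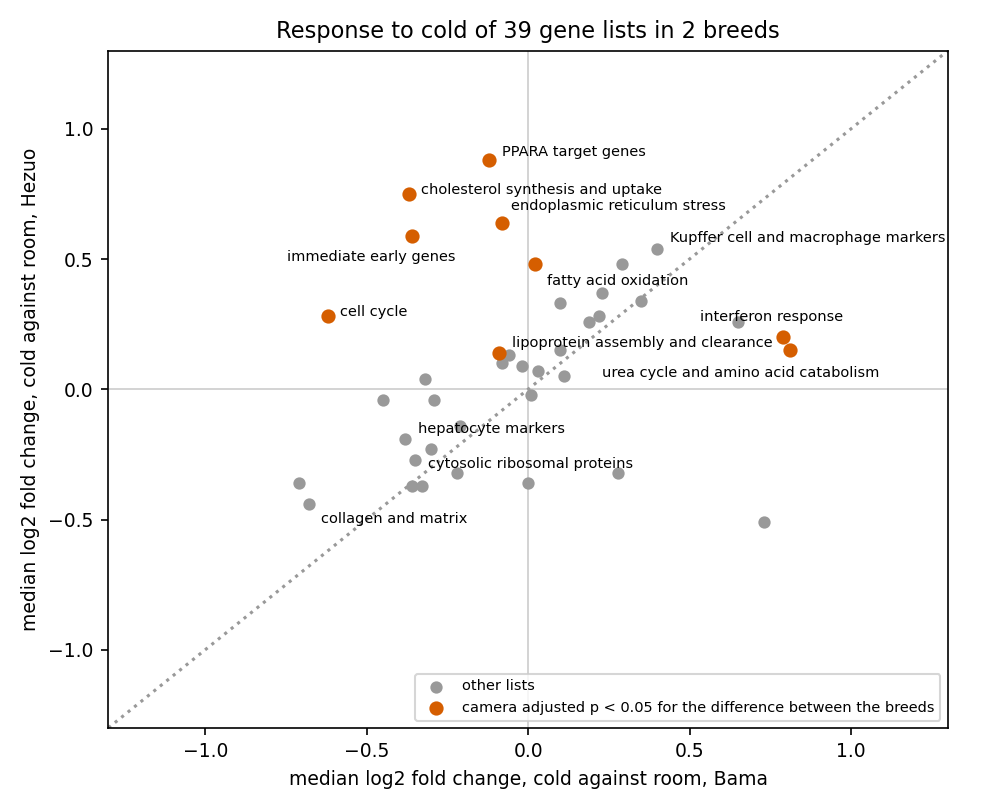
Median log2 fold change (cold against room temperature) of each of 39 gene lists in Bama pigs (x axis) and Hezuo pigs (y axis); each point is 1 list and the dotted line marks equal values. The 9 lists in orange had a camera adjusted p below 0.05 for the difference between the breeds, among them PPARA targets (difference 1.1) above the line and the urea cycle and amino acid catabolism (difference -0.8) below it.

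Back-splice reads per 1000000 gene counts averaged 2279 ± 311 in Bama pigs at room temperature, 2077 ± 187 in Bama in the cold, 1952 ± 103 in Hezuo at room temperature and 1820 ± 144 in Hezuo in the cold (SD, n = 3). The difference between cold and room temperature was -132 in Hezuo pigs (exact permutation p = 0.5, adjusted 0.667) and -202 in Bama pigs (exact permutation p = 0.6, adjusted 0.72). It was -167 over both breeds (permutation within breeds p = 0.205, adjusted 0.351; -242 to -87 on leaving out 1 library). Hezuo against Bama gave -327 at room temperature (exact permutation p = 0.2) and -257 in the cold (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow), both 0.351 after adjustment. Over both temperatures, a comparison not planned beforehand, the breeds differed by -292 (exact permutation p = 0.025, adjusted over 12 tests 0.3). At an equal depth of 39117 back-splice reads, 8962 ± 256, 8574 ± 260, 8615 ± 167 and 8540 ± 400 circRNAs were detected in the same order of groups, and the cold over both breeds gave -232 (exact permutation p = 0.175, adjusted 0.351; -331 to -131 on leaving out 1 library). The highest mean raw counts over all libraries were those of circRNAs from NECTIN3 on chromosome 13 from 148517273 to 148534946, with 604 (246 to 1967, the highest in 1 Bama cold library) and TUT7 on chromosome 10 from 29037750 to 29038934 (464). In Hezuo pigs at room temperature TUT7 was above NECTIN3 (means of 509 and 332).

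In cold-exposed Hezuo pigs a circRNA of AKR1D1, a bile acid enzyme gene, on chromosome 18 from 11436848 to 11447863 fell from 160 to 207 counts per library to 47 to 102 (-1.23 ± 0.25, adjusted p = 0.00154). In Bama pigs it fell from 212 to 296 counts to 71 to 97 (-1.19 ± 0.25, adjusted p = 0.00118), while its host gene had -0.29 (adjusted p = 0.483) and -0.82 (adjusted p = 0.0785), and was called lower over both breeds (-0.55, adjusted p = 0.0456). The Hezuo call of this circRNA was lost without Hezuo room temperature replicate 3 (-1.09, adjusted p = 0.187) or Hezuo cold replicate 2 (-0.98, adjusted p = 0.245). In Hezuo pigs a circRNA of ITIH4 on chromosome 13 from 34928536 to 34929490 rose from 1 to 8 counts to 7 to 45 (2.37 ± 0.53, adjusted p = 0.0117). An intergenic circRNA on chromosome 6 from 14926250 to 14926563 rose from 4 to 11 counts to 17 to 74 (2.38 ± 0.45, adjusted p = 0.000664). Both calls were lost without Hezuo room temperature replicate 3 (adjusted p = 0.456 and 0.0634) or Hezuo cold replicate 2 (0.899 for both). A circRNA of CYP3A39 on chromosome 3 from 6746550 to 6758714 had 0 to 1 counts at room temperature and 1 to 50 in the cold (adjusted p = 1.25e-08), while another from 6651530 to 6660663 fell from 2 to 54 counts to 0 to 2 (-3.8 ± 0.75, adjusted p = 0.00126). Both are uncertain because the family holds similar copies. In Hezuo pigs 8 circRNAs of 9032 were called, 5 higher and 3 lower in the cold, and with a library size from the gene counts 5 were called, 2 higher and 3 lower. DESeq2 called 3, and the newer method of edgeR 1. The count was 2 without Hezuo room temperature replicate 3 or Hezuo cold replicate 2, 5 without Hezuo room temperature replicate 2, and 16 without Hezuo cold replicate 1.

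In Bama pigs 3 circRNAs of NDFIP2, an adaptor of NEDD4 ubiquitin ligases, that share a start at 51531489 on chromosome 11 rose in the cold. The one ending at 51540684 rose from 92 to 105 counts to 141 to 408 (1.84 ± 0.24, adjusted p = 1.41e-10). The one ending at 51554792 rose from 35 to 62 counts to 61 to 302 (2.15 ± 0.3, adjusted p = 5.14e-09) and the one ending at 51547197 from 21 to 34 counts to 59 to 179 (2.24 ± 0.34, adjusted p = 1.69e-07). Their host gene had 0.95 (adjusted p = 0.131). Without Bama cold replicate 3 the call of the circRNA ending at 51554792 was lost (1.33, adjusted p = 0.0751). A circRNA of CNTRL, a protein of the centrosome, on chromosome 1 from 261142021 to 261155614 fell from 10 to 48 counts to 3 to 7 (-2.3 ± 0.46, adjusted p = 0.000688), a call lost without Bama room temperature replicate 2 (-1.76, adjusted p = 0.286). One of PECR, a peroxisomal enoyl-CoA reductase, on chromosome 15 from 118320252 to 118327364 fell by 2.63 on the log2 scale (adjusted p = 0.0045), a call lost without Bama room temperature replicate 1 (adjusted p = 0.325) or Bama cold replicate 3 (0.175). Among the 14 circRNAs called, 10 higher and 4 lower, were 2 of chromosome Y, seen in 0 of 3 Bama libraries at room temperature. With a library size from the gene counts 14 were called, 7 higher and 7 lower, and with Y-linked RNA as a covariate 4.

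Over both breeds, 18 circRNAs were called for cold, 13 higher and 5 lower, and 29 with a library size from the gene counts, 9 higher and 20 lower. The choice of library size moved the median log2 fold change of all circRNAs from -0.063 to -0.245 in this comparison, from 0 to -0.124 in Hezuo pigs and from -0.073 to -0.305 in Bama pigs. It went from -0.023 to 0.115 between the breeds in the cold and from 0.068 to 0.164 in the difference between the responses. The AKR1D1 circRNA (-1.21 ± 0.17, adjusted p = 1.68e-08) and the NDFIP2 circRNAs ending at 51554792 (1.62 ± 0.22, adjusted p = 7.09e-10) and 51540684 (1.07 ± 0.17, adjusted p = 3.52e-07) were called in all 12 fits that left out 1 library. So was that of ITIH4 (2.19 ± 0.35, adjusted p = 9.55e-07).

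Between the breeds, an antisense circRNA at MT1A on chromosome 6 from 18661906 to 18667566 had 0 counts in the 6 Bama libraries, 71 to 138 in Hezuo pigs at room temperature and 77 to 89 in the cold (adjusted p = 1.53e-46 and 2.75e-40). It is uncertain because metallothionein genes have similar copies and the counting is not stated to use strand. An unnamed circRNA on chromosome 7 from 115947803 to 115983170 had 25 to 57 counts in Bama pigs at room temperature and 0 in Hezuo pigs (adjusted p = 2e-10). One on chromosome 7 from 20720396 to 20737650 had 14 to 64 against 0 (adjusted p = 1.04e-13). At room temperature a circRNA of AASS, the first enzyme of lysine breakdown, on chromosome 18 from 24985702 to 25003037 was higher in Hezuo pigs with 96 to 180 against 30 to 53 counts (1.94 ± 0.27, adjusted p = 4e-09). Its host gene had 1.22 (adjusted p = 0.177). In the cold, circRNAs of PPP2R1B on chromosome 9 from 39494895 to 39504434 (34 to 56 against 4 to 12 counts, 2.52 ± 0.43, adjusted p = 5.98e-06) and CNTRL on chromosome 1 from 261142021 to 261155614 (2.68 ± 0.46, adjusted p = 6.71e-06) were higher. A circRNA of SOX5 on chromosome 5 from 49813301 to 49859235 was lower with 7 to 31 against 40 to 149 counts (-2.27 ± 0.36, adjusted p = 5.62e-07). These calls held in all 12 fits that left out 1 library. At room temperature 41 circRNAs were called, 25 higher and 16 lower in Hezuo pigs, and in the cold 38, 19 higher and 19 lower. With a library size from the gene counts 42 were called in the cold, 27 higher and 15 lower. DESeq2 called 22 and 25, and with Y-linked RNA as a covariate 2 were called at room temperature. Without Bama room temperature replicate 2 or 3 the room temperature count was 27 and 26. For the difference between the responses to cold, 8 circRNAs were called, 2 with a higher and 6 with a lower response in Hezuo pigs. With a library size from the gene counts 2 were called, 1 higher and 1 lower. DESeq2 called 2, a minimum of 30 counts left 5, Y-linked RNA as a covariate 1 and the newer method of edgeR 4. The count was 1, 5 and 2 without Bama room temperature replicates 1 to 3, and 4 and 1 without Bama cold replicates 1 and 3. It was 3 without Hezuo room temperature replicate 1 or 2, and 4 and 3 without Hezuo cold replicates 2 and 3.

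**Figure D4:**
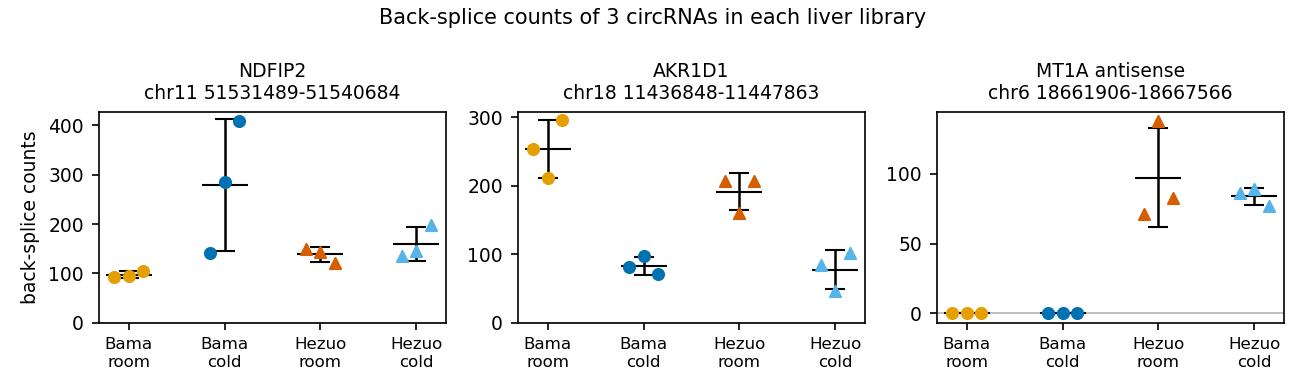
Back-splice counts per library, not scaled for depth, of 3 circRNAs in the 4 groups, from NDFIP2 (chromosome 11, 51531489 to 51540684), AKR1D1 (chromosome 18, 11436848 to 11447863) and antisense to MT1A (chromosome 6, 18661906 to 18667566); points are single pigs, and bars give the mean and SD (n = 3). The NDFIP2 circRNA reaches 408 counts in Bama pigs in the cold, the AKR1D1 circRNA is lower in the cold in both breeds, and the MT1A antisense circRNA has 0 counts in all Bama libraries.

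Across 8790 circRNAs with a tested host gene (3221 hosts), the log2 fold changes of circRNA and host correlated at Pearson r = 0.1 and Spearman rho = 0.11 for cold in Hezuo pigs, and 0.196 and 0.138 for cold in Bama pigs. The values were 0.15 and 0.101 between the breeds at room temperature, 0.137 and 0.132 in the cold, 0.105 and 0.08 for the difference between the responses, and 0.187 and 0.154 for cold over both breeds. With at least 30 counts, Pearson r was 0.133, 0.315, 0.253, 0.163, 0.171 and 0.28 in the same order. CircRNAs are not independent replicates, so no p is given.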

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

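Of the tests below, those of fatty acid oxidation and the splits of genes and circRNAs within each breed and between the breeds at room temperature were chosen after their results were seen. The results listed first differed between the breeds in the response to cold by a test of that difference. In Bama pigs that response goes with a change in Y-linked RNA (0 of 3 libraries at room temperature, 2 of 3 in the cold). The 2 cannot be fully told apart. MAGED1 moved in opposite directions in the 2 breeds, with a difference of 2.32 on the log2 scale, and was the 1 gene called. Other splits of the samples do not exclude chance for that count: 14 of 100 gave as many, and the highest other, 526, is the real grouping with 1 breed mirrored, which is a structure of the samples. Among circRNAs the largest called difference was 9.99 for CYP3A39 on chromosome 3 from 6746550 to 6758714, with 5 to 28 counts in Bama at room temperature, 0 to 1 in Bama in the cold, 0 to 1 in Hezuo at room temperature and 1 to 50 in Hezuo in the cold. CYP2C33 on chromosome 14 from 111253510 to 111282469 had 5.06, with 7 to 25, 0 to 21, 0 to 1 and 2 to 14 counts in the same order. The NDFIP2 circRNAs from 51531489 on chromosome 11 had -2.3 (to 51547197; 21 to 34, 59 to 179, 22 to 30 and 12 to 31 counts) and -1.55 (to 51540684; 92 to 105, 141 to 408, 122 to 150 and 136 to 199). SLC38A1 on chromosome 5 from 77049090 to 77058522 had -2.78 (6 to 13, 30 to 42, 12 to 27 and 7 to 17 counts). An unnamed circRNA on chromosome 17 from 5052491 to 5077828, named after its values were seen, had -5.24 (0 to 2, 8 to 14, 6 to 13 and 1 to 5 counts). The circRNAs of chromosome Y from 9399938 to 9414823 and from 9910950 to 9917192 had -5.71 and -6.69 and were at 0 in Bama pigs at room temperature, where no library held Y-linked RNA. Of these 8, the call of CYP3A39 held in all 12 fits that left out 1 library, and splits do not exclude chance for the count (8 of 100 as large; highest other 18).

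Among the lists, the median difference in response was 1.11 for immediate early genes, 1.1 for PPARA targets, 0.97 for the cell cycle, 0.86 for cholesterol synthesis and uptake, 0.58 for endoplasmic reticulum stress, 0.52 for fatty acid oxidation, 0.13 for lipoprotein genes, -0.56 for interferon response and -0.8 for the urea cycle and amino acid catabolism. Chance is not excluded for the count of 9 lists, since 84 of 100 splits gave as many and the highest other gave 22.

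One pattern among these lists is fatty acid oxidation, higher in Hezuo than in Bama livers in the cold by a median of 0.67. Y-linked RNA, absent from Bama cold replicate 2, is argued against as the source: without that library the list kept 0.99 of its median log2 fold change (0.8 to 1.62 on leaving out 1 more cold library). A lower share of hepatocytes in Bama livers in the cold would go with hepatocyte markers at 0.5 and T and NK cell markers at -0.95 between the breeds in the cold, and with hepatocyte markers at -0.38, Kupffer cell markers at 0.4 and neutrophil markers at 0.73 for cold in Bama pigs. Other markers cannot decide it, since more of 1 cell type lowers the share of every other. Endothelial markers were higher in Hezuo livers in the cold (median 0.29, and 0.16 to 0.36 on leaving out 1 cold library), and stellate markers fell in Bama pigs in the cold (-0.33, and -0.44 to -0.22 on leaving out 1 Bama library). The hepatocyte share stays open, as do more immune cells, breed, age and feeding, which were not tested.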

How the results depend on the processing

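The fits with Y-linked RNA as a covariate, with the newer method of edgeR and without Bama cold replicate 2 as a doubted library were chosen after seeing the data, as was the tolerance of 0.1 for a changed correlation of responses. Unless stated otherwise, the cause of a change below was not tested. Of 136 called values of single genes, all 136 kept their direction and call with the size factors of DESeq2 and with the newer method, 134 with the test of DESeq2, 126 with no filter, 127 of 127 with at least 1 CPM in 6 libraries, 72 with a replicate block, 50 of 105 in fits on only the 2 groups compared, 69 to 110 on leaving out 1 library and 22 with the covariate. Called lists (94 over the 6 comparisons) kept their call in 94 cases with the size factors and in 77 with the covariate. In the order cold in Hezuo, cold in Bama, breeds at room temperature, breeds in the cold, difference between the responses and cold over both breeds, gene counts were 540, 682, 1036, 1227, 139 and 1491 with DESeq2, and 3, 1, 3, 132, 0 and 6 with the covariate, where 737 genes had an unadjusted p below 0.05 beside the 0 and DESeq2 without the covariate called 139. Fits on only the 2 groups gave 60 (cold in Hezuo), 12 (cold in Bama) and 116 (breeds in the cold), and the newer method 231 for the breeds at room temperature.

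Same-numbered pigs of different groups deviated little together (3 of 18 pairs had r over 0.1, range -0.198 to 0.148). With 3 pigs per group this does not exclude pairing. Across temperatures the Bama pairs (0.022 to 0.148) lay above pairs of unlike number (0.008 at most), but the Hezuo pairs did not. With a replicate block edgeR called 0 genes for cold in Hezuo (2050 at an unadjusted p below 0.05), 67 for cold in Bama, 35 between the breeds at room temperature and 5 circRNAs for the difference between the responses; no other count moved by over 1.5 times.

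CircRNA counts became 3 (cold in Hezuo), 22 and 25 (breeds at room temperature and in the cold) and 2 (difference between the responses) with DESeq2; 5 (cold in Hezuo), 2 (difference) and 29 (cold over both breeds) with a library size from the gene counts; 1 (cold in Hezuo) and 5 (difference) with at least 30 counts in all; 4 (cold in Bama), 2 (breeds at room temperature) and 1 (difference) with the covariate; and 1 (cold in Hezuo) and 4 (difference) with the newer method. Lists called numbered 0 in all 6 comparisons with an estimated correlation, and 0, 0, 0, 9, 0 and 0 with directional fry. The correlation of the responses was 0.144 with the covariate, and that of circRNAs with their hosts 0.133 to 0.315 with at least 30 counts (0.28 for cold over both breeds). With the covariate these turned or went to 0: DDX3Y -4.22 and EIF1AY -1.91 (adjusted p = 0.574 and 0.86) and the collagen list (adjusted p = 0.678) between the breeds at room temperature; the circRNA of chromosome Y from 9399938 at 0 (cold in Bama), -1.02 (breeds at room temperature) and 0.98 (difference), and that from 9910950 at 0 and -0.5 in the first 2. The covariate is itself Y-linked RNA, which removes those of chromosome Y by construction.

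Leaving out 1 library at a time gave 0 to 66 genes for cold in Hezuo (lowest without Hezuo room temperature replicate 1 or Hezuo cold replicate 3), 18 to 133 for cold in Bama, 8 to 593 between the breeds at room temperature (highest without Bama room temperature replicate 2), 69 to 423 in the cold, 1 to 23 for the difference and 130 to 606 for cold over both breeds. CircRNA counts ran from 2 to 16 for cold in Hezuo, 26 to 44 between the breeds at room temperature and 1 to 8 for the difference, and list counts from 7 to 15 for the difference. Of the called genes 0, 14, 8, 47, 1 and 108, and of the circRNAs 1, 6, 16, 17, 1 and 7, were called in all 12. The circRNA tests recovered 8% of simulated 4-fold changes, and the part of depth was not tested. Pseudocount alternatives for FPKM did not apply, since counts were tested.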

Other observations

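The test of Y-linked RNA for the breeds at room temperature and that of circRNA hosts were written before their results were seen, while the circRNAs of 1 breed alone were picked from the data. Several lists were called in no comparison. Glycolysis rose in 2 of 21 genes over all genes tested and in 4 adjusted over the list alone for cold over both breeds (median 0.11, camera adjusted p = 0.176), and the list of uncoupling and futile cycles in 1 of 15 (camera adjusted p = 0.448). The thyroid hormone axis moved both ways, with 2 of 13 rising and 1 falling over all genes, and 3 and 5 adjusted over the list alone (median -0.15, camera adjusted p = 0.902). Acute-phase proteins did the same, with 1 of 22 rising and 2 falling (median 0.32, camera adjusted p = 0.345). Neutrophil markers had medians of 0.73 for cold in Bama pigs (camera adjusted p = 0.202) and -0.51 in Hezuo pigs (0.813), with a difference of -0.95 (0.279). Liver endothelial markers had 0.29 between the breeds in the cold, with 2 of 17 higher over all genes (0.0926), cholangiocyte markers -0.18 (0.34) and B and plasma cell markers -0.36 (0.176) for cold over both breeds. Cold-inducible RNA-binding proteins and ketogenesis had 4 tested genes each and were not tested as lists; 1 cold-inducible gene was lower over the list alone and in DESeq2 for cold in Bama pigs and over both breeds, and in the cold 1 ketogenesis gene was higher in Hezuo than in Bama livers over all genes tested (median of the list 0.77).

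Erythroid markers were called higher as a list in Hezuo than in Bama livers at room temperature (median 1.52, camera adjusted p = 0.0118, adjusted p = 0.718 with an estimated correlation) and in the cold (1.65, 0.00165, and 0.548 with an estimated correlation). In edgeR 0 of 12 members passed over all genes in either; in the cold 1 was higher and 1 lower over the list alone and in DESeq2, and 6 and 1 at an unadjusted p below 0.05. The room temperature call was lost without Bama room temperature replicate 2 (adjusted p = 0.0551) or Hezuo room temperature replicate 2 (0.113). In the cold cholesterol synthesis and uptake (0.53), nuclear respiratory chain genes (0.17) and immediate early genes (0.28) were called higher in Hezuo pigs as well, and none with an estimated correlation (adjusted p = 0.656, 0.618 and 0.656). In the last 2 edgeR called 0 members by either adjustment, with 11 of 72 and 6 of 22 at an unadjusted p below 0.05 and 3 each in DESeq2. The cholesterol call was lost without Bama cold replicate 1 (0.132) or Hezuo cold replicate 2 (0.12), and that of immediate early genes without Bama cold replicate 3 (0.339) or Hezuo cold replicate 3 (0.273).

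At room temperature every Hezuo and no Bama library held Y-linked RNA, so the 146 genes called between the breeds might mark sex. In the cold without Bama cold replicate 2, where all 5 remaining libraries held it, the median log2 fold change of these genes was 0.53 of that at room temperature (0.45 to 0.62 on leaving out 1 more cold library), with 129 of 146 in the same direction, and 23 called in that and 1 in the other direction. A value under 0.25 was set beforehand as what sex alone would give, and one over 0.5 as what breed would give, and the range spans the latter, so the part of sex cannot be told apart from that of breed for the set. The breed stays an open explanation.

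There were 17 circRNAs counted in all 6 libraries of 1 breed and in none of the other (8 Hezuo, 9 Bama), and the 461 other splits into 6 and 6 gave at most 13. A missing host transcript is argued against as the source for the set, since the 14 tested hosts were higher in the breed with the circRNA by a median of only 0.18 (0.15 to 0.21 on leaving out 1 host). The largest host differences, Hezuo against Bama, were 1.12 for MT1A and -1.43 for the circRNA on chromosome 7 from 20720396 to 20737650. The latter host had -2.32 at room temperature (adjusted p = 0.0696) and -0.55 in the cold (0.601). MT1A RNA cannot test its antisense circRNA's source. Reads shared between similar copies and a breed variant against the reference could not be tested without a genome.

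For the counts of called genes, 100 splits of the samples within breeds exclude chance for cold over both breeds (526 real, 59 highest other). The 10 splits of 6 libraries are too few for the other comparisons, with 38 real and 1 highest other for cold in Hezuo, 125 and 32 for cold in Bama, 146 and 0 between the breeds at room temperature and 374 and 0 in the cold. For circRNAs chance is excluded for cold over both breeds (18 and 15), not for cold in Hezuo (8 and 9), and the splits are too few for the rest (14 and 3, 41 and 2, 38 and 8). For lists they are too few for 13 and 15, 14 and 20, 21 and 21, and 18 and 21, and chance is not excluded for cold over both breeds (19 real, 23 highest other, 7 of 100 as large).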
